A study of Homo sapiens with 12 samples.

How the data were processed

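Total RNA from MDA-MB-231, a human triple-negative breast cancer cell line, was hybridised to 12 Illumina bead arrays, 1 array per sample and 1 colour per array. Cells carried a negative control siRNA (siNC) or an siRNA against EZH2, RELA or RELB, and were left without TNFalpha (CTRL) or given 10 ng/ml TNFalpha for 4 h (TNF). Groups and replicate numbers come from the sample titles. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

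The authors deposited a probe table of average signal intensity, on a linear scale, with no normalization, per the file headers. The submitters' processing notes name BeadStudio 3.2.7. The deposited detection columns hold a score that rises with signal. In 1 table these columns are headed as p-values, and their values are nevertheless that score, so 1 minus the score was used as the detection p. A count of beads per probe stands beside each signal. Each of the 22184 entries of another deposited signal table equalled 1 entry of this table, and tied probes to gene names. A further deposited table holds the authors' processed values on a log2 scale. Set against the signals over 4621 bright probes, these values equalled log2 signal minus the array's 75th percentile and minus a centre per probe. That centre was computed separately for replicates 1 and 2 of siNC CTRL and siEZH2 CTRL (the first processing set, 4 arrays) and for the other 8 arrays (the second set). Within a set the remaining differences had an SD of at most 5.44e-07, and between sets of at least 0.330. Scale and centring were thus read from the values, the direction is that of signal, and the tool for that step is not given in the sources used here. Column medians of these values were -0.0267, 0.0134 and 0.0283 for siNC CTRL replicates 1, 2 and 3, -0.0544, 0.0518 and 0.214 for siEZH2 CTRL replicates 1, 2 and 3, 0.0694 for siNC TNF, 0.198 for siEZH2 TNF, -0.0663 and -0.0140 for siRelA CTRL and TNF, and -0.116 and -0.0377 for siRelB CTRL and TNF. They served as an alternative only.

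Signals were background-corrected with limma 3.58.1 (R 4.3.3) by the normal-exponential method, with the negative control level taken from the detection p, then raised by an offset of 16, quantile normalized over the 12 arrays and put on a log2 scale. A probe was kept if its detection p was under 0.05 on at least 3 of the 12 arrays, which left 13884 probes. Gene names were those of the probe table, updated through a gene table of assembly GRCh38.p14 used for names only. Of the 22184 probes, 17828 carried a current symbol, 3293 were updated by a synonym, 889 matched neither and kept the file's name, and 174 kept it because the synonym was ambiguous. For each of the 12275 genes the kept probe with the highest mean intensity was used. Probes of 1 gene disagreed for ERBB3 and FBXO32 among the genes named in the results. Genes with near-identical copies (CST1, DEFB103A, KRTAP2-4) are uncertain, and DOC1 is the file's own name, which several genes have shared.

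Background, taken as the median signal of undetected probes, was 58.1 to 101.5, the highest values being those of the siNC CTRL and siEZH2 CTRL arrays of replicate 2 (101.5 and 99.7) and no other array exceeding 80.1. Between 55.6% and 58.2% of probes were detected per array. Probes were read from a mean of 40.8 to 43.1 beads on 11 arrays and from 23.6 on the siNC TNF array. Precision is limited by the number of arrays.

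Tests used limma (lmFit and eBayes) with Benjamini-Hochberg adjustment at 0.05. siEZH2 against siNC without TNF (3 arrays against 3) and the siEZH2 by TNF interaction came from a fit with a mean per group. The TNF response, siRelA against siNC and siRelB against siNC came from an additive fit of siRNA and TNF over all 12 arrays, in which each siRelA or siRelB comparison sets 2 arrays against 4. The interaction, and any alternative with 1 array in an arm, assumes that the lone array varies like the replicated groups. TNF responses within each siRNA rest on 1 TNF array and are given as values without a p, with the percentile of each list median among 10000 random lists of the same size matched on mean intensity in 20 bins. Where a gene was not detected on any array of 1 arm, the fold is a bound, computed against the higher of the gene's own value and the lowest value of a detected probe on each array of that arm. It is written as "at least N-fold". A fitted log2 change of such a gene is not a bound.

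The 16 gene lists held NF-kB target cytokines and chemokines, NF-kB pathway feedback genes, NF-kB target adhesion, survival and tissue genes, interferon-stimulated genes, Polycomb repressive complex 2 (PRC2) components, genes described elsewhere as silenced by EZH2 in cancer lines, DNA replication genes, mitosis genes, mesenchymal genes, epithelial and luminal breast genes (markers of another breast line), blood cell markers (another cell type), p53 targets, genes of the unfolded protein and integrated stress response, cholesterol biosynthesis genes, immediate early genes and hypoxia genes. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 16 lists within a comparison, and again with an estimated correlation. The latter option also takes its degrees of freedom from the few arrays, which raises p whatever the correlation. With siEZH2 the DNA replication list had an estimated correlation of -0.015, below the preset, yet its camera adjusted p went from 2.58e-09 to 0.032. A call lost with that option is therefore not by itself a sign of genes that vary together. Named genes were the siRNA targets, the 8 largest rises and 8 largest falls past the threshold with no overlap between the arms (for siRelA and siRelB, with the same sign in both TNF states), up to 3 members past the threshold per list and up to 6 per NF-kB list, and IL6, CXCL8, TNF, CXCL1, NFKBIA, TNFAIP3, BIRC3 and ICAM1 whatever their value. For single arrays the 5 largest rises and falls among genes detected on all arrays compared were eligible. A gene named outside this rule was chosen after its values were seen, as the text says where it occurs. Some genes that the rule names are not reported here. Overlaps between siRNA comparisons were set against the product of the list sizes divided by the number of genes, and against 100 simulations of unchanged groups that shared the siNC arrays.

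The groups, fits, gene lists, naming rule and first alternatives were fixed before the data were examined. The first alternatives were no background correction, normexp with an offset of 50, median scaling in place of quantile, the authors' processed values, other detection filters, the mean of a gene's probes, an intensity trend with robust estimation, leaving out each array, other models, and the replicate number as a block for siEZH2. Chosen after the data were seen were the 2 processing sets analysed alone or as a term, leaving out both replicate 2 arrays, the replicate block for the other comparisons, separate siNC arrays for the overlap, and replicate 3 alone as control. A slide block was not run because the files name no slides. Same-numbered siNC CTRL and siEZH2 CTRL arrays deviated together from their group means, with correlations over genes of 0.757, 0.836 and 0.653 for replicates 1, 2 and 3, so the shared replicate numbers of the titles were taken to pair the arrays. Replicates 1 and 3 also correlated across numbers, at 0.426 (siNC 3 with siEZH2 1) and 0.418 (siNC 1 with siEZH2 3). Part of their agreement thus comes from replicate 2, which stood apart and shifts the group means. In the block for the other comparisons the 6 single arrays were placed with replicate 3, with which they share a processing set.

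On simulated data with 200 changed genes per run among 12275, the siEZH2 fit called 46.7% of genes changed by 1 on the log2 scale and 96.7% of those changed by 2. For the same sizes the siRelA fit called 57.6% and 95.5%, the siRelB fit 58.8% and 94.9%, the TNF fit 81.8% and 98.8%, and the interaction fit 0.606% and 40.9%. Simulated lists of 20 genes shifted by 0.5 were called in 100 of 100 cases in each comparison, at the preset correlation only. The simulated genes varied independently, without the shared deviations of same-numbered arrays. The estimated correlation of the measured mitosis list was 0.638 in the siEZH2 comparison. These shares therefore do not give the power for genes and lists that vary together.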

Results

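Gene expression was measured on 12 bead arrays in MDA-MB-231, a triple-negative breast cancer cell line with high basal NF-kB activity. Cells had received a control siRNA (siNC) or an siRNA against EZH2, the histone methyltransferase of Polycomb repressive complex 2, or against RELA or RELB, which encode NF-kB transcription factor subunits. They were harvested without TNFalpha or after 4 h with 10 ng/ml TNFalpha, a cytokine that activates NF-kB. The siNC and siEZH2 groups without TNF had 3 arrays each, and the other 6 groups had 1 array each. Between 12337 and 12908 probes were detected per array, over a median background signal of 58.1 to 101.5. Values below are normalized log2 intensities, and errors of log2 changes are standard errors (SE).

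The targeted genes were lower with their own siRNA. EZH2 averaged 8.90 ± 0.52 (SD, n = 3) with siNC and 6.12 ± 0.57 (SD, n = 3) with siEZH2 in cells without TNF, a 6.85-fold lower level (log2 change -2.78 ± 0.365, limma adjusted p = 0.00538), and a further EZH2 probe changed by -3.71. On single arrays EZH2 was 6.61 with siEZH2 and TNF, and lay between 9.23 and 9.52 with siNC and TNF, siRelA or siRelB. RELA was not detected on either siRelA array (5.03 without TNF and 5.00 with TNF), at least 3.44-fold lower than with siNC (adjusted p = 0.00164), and lay between 6.61 and 7.71 on the other 10 arrays. RELB was 5.56-fold lower with siRelB (log2 change -2.48 ± 0.23, adjusted p = 0.000597). RELB was also 4.51-fold lower with siRelA (-2.17 ± 0.23, adjusted p = 0.0013). With siEZH2, RELA changed by 0.25 ± 0.25 (adjusted p = 0.617) and RELB by -0.65 ± 0.21 (adjusted p = 0.0919), which passed with the replicate block (adjusted p = 0.00646).

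**Figure D1:**
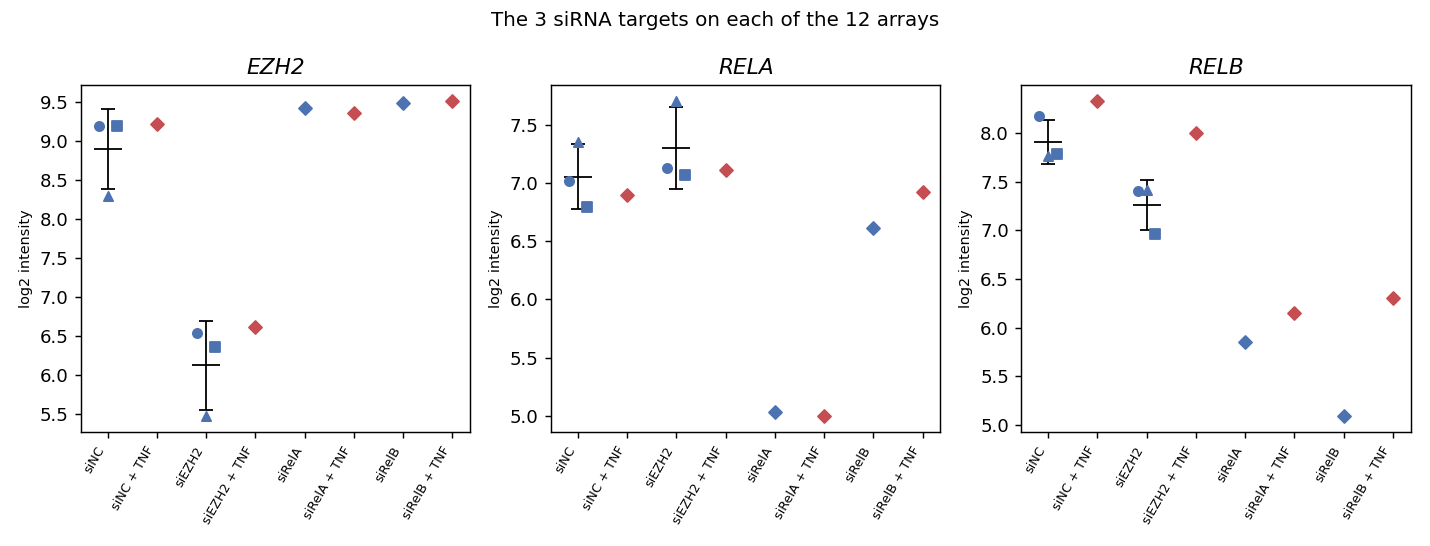
Normalized log2 intensity of EZH2, RELA and RELB on each of the 12 arrays, by siRNA, with arrays without TNF in blue and with TNF in red. Circles, triangles and squares are replicates 1, 2 and 3, diamonds are groups of 1 array, and black bars give the mean ± SD of 3 arrays. EZH2 lies at 6.61 or below on the 4 siEZH2 arrays, and RELA at 5.03 and 5.00 on the siRelA arrays.

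The first comparison asked which genes depend on EZH2 in cells without TNF. Among the largest rises with siEZH2, CST1, a secreted cystatin protease inhibitor whose probe may not separate it from near-identical family members, was 47.4-fold higher (log2 change 5.57 ± 0.74, n = 3 against 3, adjusted p = 0.00538). PLD5, a phospholipase D family member not detected with siNC, was at least 15.1-fold higher. The neuroendocrine chaperone SCG5 rose 13.2-fold, the calcium-binding protein gene CALB2 13.1-fold, the carboxypeptidase gene CPA4 11.7-fold and IGFBP3, an insulin-like growth factor carrier, 10.5-fold. ESM1, a secreted endothelial proteoglycan, rose 10.8-fold, and the defensin DEFB103A, which has a near-identical gene copy, 10.4-fold. DEFB103A lost its call in 11 alternatives. Among these were no background correction, the authors' processed values and leaving out any array but siEZH2 replicate 2. The largest falls included CEMIP, a hyaluronan-degrading protein gene (15.2-fold lower, -3.93 ± 0.43, adjusted p = 0.00374), the peptidase gene THOP1 (8.81-fold), the cytokine gene IL6 (8.39-fold), the cytokine gene IL11 (7.15-fold), DSCC1, which acts in sister chromatid cohesion (6.99-fold), CDCA3, a cell cycle ubiquitin ligase cofactor (6.95-fold), and OIP5, a centromere protein gene (6.89-fold).

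NF-kB target cytokines and chemokines fell with siEZH2. Of 22 measured members, 12 fell and 10 did not pass, and adjusted over the list alone 13 fell and 1 rose. The list median was -1.49 (camera adjusted p = 1.7e-06, and adjusted p = 0.141 with an estimated correlation). IL6, an inflammatory cytokine, averaged 11.34 ± 0.89 (SD) with siNC and 8.27 ± 0.27 with siEZH2 (log2 change -3.07 ± 0.43, adjusted p = 0.00631). CXCL10 and CXCL11, T cell-attracting chemokines, were 6.78-fold and at least 4.48-fold lower, and the granulocyte growth factor CSF3 was at least 4.49-fold lower. CXCL8, a neutrophil chemokine, fell 3.85-fold (adjusted p = 0.0152), CSF2, a myeloid growth factor, 4.30-fold (adjusted p = 0.0352), and CXCL1, another neutrophil chemokine, 3.24-fold (adjusted p = 0.0252), and TNF was at least 1.72-fold lower. Leaving out siEZH2 replicate 1, siNC replicate 3 or siEZH2 replicate 3 gave CXCL8 an adjusted p of 0.0661, 0.0503 and 0.0533, and CXCL1 one of 0.0666, 0.066 and 0.0646. CXCL1 was also lost without siEZH2 replicate 2 (0.0546) and in the second processing set alone (log2 change -0.39, adjusted p = 0.274). CSF2 was lost without siNC replicate 1 (0.103), siEZH2 replicate 1 (0.0562), siNC replicate 3 (0.113) or siEZH2 replicate 3 (0.0657). Its call was also lost under median scaling, without a detection filter, and in the authors' processed values without or with a set term.

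NF-kB feedback genes, which limit or sustain the pathway, had a median of -0.48 with siEZH2 (camera adjusted p = 0.0039, and adjusted p = 0.258 with an estimated correlation), and of -0.16 in the second processing set alone (adjusted p = 0.418). Of 21 members 4 fell, and 5 fell adjusted over the list alone. BIRC3, an inhibitor of apoptosis, fell 2.36-fold, the NF-kB subunit NFKB2 1.95-fold, TNIP1, a partner of the ubiquitin-editing enzyme A20, 1.81-fold and the kinase RIPK2 1.72-fold. All 4 calls were lost without siNC replicate 3, siEZH2 replicate 1 or siEZH2 replicate 3. BIRC3 and TNIP1 were also lost in the second processing set alone, BIRC3 with the mean of its probes, and NFKB2 in the authors' processed values. NFKBIA, the NF-kB inhibitor, changed by -1.23 ± 0.35 (adjusted p = 0.0587) and TNFAIP3, which encodes A20, by -0.19 ± 0.27 (adjusted p = 0.75), so neither passed. With the replicate block NFKBIA passed (adjusted p = 0.00031), TNFAIP3 did not (0.293), and 10 of the 21 members fell. Among the 22 NF-kB adhesion, survival and tissue genes 4 rose and 2 fell, 4 rose and 4 fell adjusted over the list alone, and the list did not shift as a whole (median -0.38, camera adjusted p = 0.667). ICAM1, a leukocyte adhesion receptor, rose 4.05-fold, and the matrix metalloproteinases MMP3 and MMP1 3.42-fold and 3.31-fold. The heparan sulfate proteoglycan SDC4 fell 2.46-fold and TNFAIP2 2.09-fold. ICAM1 averaged 7.72 ± 0.75 (SD) with siNC and 9.73 ± 0.52 with siEZH2, and its adjusted p of 0.0217 rose to between 0.0512 and 0.0868 when any array but siNC replicate 2 was left out, as did that of MMP1, to between 0.0802 and 0.132.

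Cell cycle genes fell with siEZH2. All 30 mitosis genes had negative changes and 21 of them fell (29 adjusted over the list alone), with a median of -1.50 (camera adjusted p = 1.91e-15, and adjusted p = 0.258 with an estimated correlation). CDC20, an activator of the anaphase-promoting complex, fell 4.43-fold, the hyaluronan receptor and spindle gene HMMR 4.22-fold and the mitotic phosphatase gene CDC25C 4.08-fold. The DNA replication list had a median of -0.64 (camera adjusted p = 2.58e-09, and adjusted p = 0.032 with an estimated correlation, which became 0.436 with the replicate block), and 10 of 31 members fell (16 adjusted over the list alone). TYMS, which makes thymidylate, fell 3.54-fold, the replicative helicase subunit MCM2 3.09-fold and the clamp loader subunit RFC4 2.67-fold. Neither list passed with siRelA or siRelB, where medians lay between 0.03 and 0.13. With siRelB the mitosis list passed as higher in the second processing set (median 0.17, adjusted p = 0.00315), without both replicate 2 arrays (0.20, adjusted p = 0.00143) and without siEZH2 replicate 2 (0.16, adjusted p = 0.00657). In the authors' values with a set term the replication list passed as higher with siRelA (adjusted p = 0.0132) and siRelB (0.0334), and the mitosis list with siRelB (0.0334).

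Hypoxia genes, p53 targets and mesenchymal genes were higher with siEZH2. The hypoxia list had a median of 0.37 (camera adjusted p = 0.00299, and adjusted p = 0.141 with an estimated correlation), with 8 of 21 members up and 1 down over all genes and adjusted over the list alone, among them ANGPTL4, a lipase inhibitor (9.25-fold), NDRG1, a stress response gene (5.53-fold), and the mitophagy receptor BNIP3L (5.06-fold). p53 targets had a median of 0.51 (camera adjusted p = 0.0288, and adjusted p = 0.175 with an estimated correlation), with 5 of 17 up and 1 down (8 and 2 adjusted over the list alone). The stress gene TP53INP1 rose 3.26-fold and SESN2, an mTORC1 inhibitor, 2.72-fold, and the DNA repair gene DDB2 fell 1.90-fold. DDB2 lost its call in 11 alternatives and TP53INP1 in 8, the authors' processed values among them. The p53 call was lost without siNC replicate 1 (adjusted p = 0.0507) or siNC replicate 3 (adjusted p = 0.0562), under the strict detection filter (0.0832) and with the mean of a gene's probes (0.0637). Mesenchymal genes had a median of 0.54 (camera adjusted p = 0.0288, and adjusted p = 0.175 with an estimated correlation), with 5 of 15 up (6 up and 1 down adjusted over the list alone), including TGFBI, an extracellular matrix protein gene (5.37-fold), the collagen gene COL1A1 (3.21-fold) and LOX, a collagen crosslinker (2.36-fold). That call was lost in the authors' processed values (adjusted p = 0.0762), in these with a set term (0.0562) and under the strict detection filter (0.12).

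Genes described elsewhere as silenced by EZH2 did not shift as a list. Of 15 members, 1 rose, also when adjusted over the list alone, which was CDKN1C, a cyclin-dependent kinase inhibitor (2.97-fold, adjusted p = 0.0131), and the median was 0.05 (camera adjusted p = 0.683). Of the 11 PRC2 components only EZH2 passed over all genes, while 1 rose and 3 fell adjusted over the list alone (median -0.28, camera adjusted p = 0.221). Under the replicate block 2 components rose and 5 fell over all genes. Interferon-stimulated genes had a median of -0.02 (camera adjusted p = 0.868) with 2 of 31 up and 4 down (3 and 4 adjusted over the list alone), among them IFI35, which fell 3.50-fold, the immunoproteasome subunit PSMB9, which fell 2.04-fold, and IFI44, which rose 1.74-fold. The stress response list had 3 of 21 up and 4 down, the same numbers adjusted over the list alone (median -0.05, camera adjusted p = 0.683). In it the chaperone HSPA5 rose 5.26-fold, while ASNS, asparagine synthetase, fell 4.23-fold and PHGDH, which starts serine synthesis, fell 3.70-fold. Epithelial and luminal genes had a median of -0.19 (camera adjusted p = 0.229), with 1 of 16 down in either adjustment, counts adjusted over the list alone included, which was EPCAM, an epithelial adhesion protein gene (2.67-fold). Of 8 blood cell markers, 1 rose and 3 fell, also adjusted over the list alone (median -0.01, camera adjusted p = 0.612), with CD14, a lipopolysaccharide co-receptor, up 2.39-fold, the actin-binding protein gene CORO1A at least 1.38-fold lower and the actin-bundling gene LCP1 down 1.89-fold. The calls of CORO1A and LCP1 were each lost in 11 alternatives and that of CD14 in 7, the authors' processed values among them. Cholesterol genes had 1 of 22 up and 1 down (1 and 0 adjusted over the list alone, median 0.13, camera adjusted p = 0.683), namely the sterol enzymes SC5D (3.03-fold up) and EBP (1.65-fold down). The list passed as higher without siNC replicate 2 (median 0.54, adjusted p = 0.0179), in the second processing set (0.32, 0.0201) and without both replicate 2 arrays (0.32, 0.0485). Immediate early genes had 2 of 17 up in either case, adjusted over the list alone included, the transcription factor KLF6 (2.14-fold) and the matricellular gene CCN2 (2.03-fold), with a median of 0.49 (camera adjusted p = 0.0795). That list passed as higher with the replicate block (0.0358, but 0.69 with an estimated correlation as well), without siNC replicate 2 (0.029), siEZH2 replicate 2 (0.00759) or both (0.00084), in the second processing set (0.00618) and without a detection filter (0.00888).

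In all, 968 genes were higher and 849 lower with siEZH2 of 12275 tested, 1817 together, of which 604 and 533 differed by over 2-fold. With the paired replicate numbers as a block the total was 5348, including all 1817 in the same direction, and within processing sets limma called 0 genes in the first set (2 arrays against 2, 1720 at an unadjusted p under 0.05) and 6272 in the second, where the siEZH2 and siNC arrays of both TNF states were used. Leaving out siNC replicate 1, siEZH2 replicate 1, siNC replicate 3 or siEZH2 replicate 3 gave 794, 725, 611 and 684 genes, and of the 63 named genes past the threshold 31 passed whichever array was left out. In the authors' processed values 21 named genes lost their call, among them EZH2 itself, TNF, CXCL11, ICAM1 and MMP1.

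The siRelA comparison, averaged over both TNF states, asked which genes depend on RELA. PTGS2, the inducible cyclooxygenase, was 31.7-fold lower (log2 change -4.99 ± 0.76, 2 arrays against 4, adjusted p = 0.00761), VNN1, a pantetheinase, at least 14.9-fold lower (adjusted p = 4.78e-07), and complement component C3 at least 14.3-fold lower. The interleukin-1 genes IL1B and IL1A fell 15.6-fold and 12.2-fold, CXCL8 13.1-fold, the collagenase MMP1 12.8-fold and LCN2, an iron-siderophore binding protein gene, 10.9-fold. Rises were smaller, with 4.95-fold for DOC1, 4.39-fold for CPA4, 4.37-fold for SERINC2, a serine incorporator, 4.33-fold for CRIP2, a LIM-domain protein gene, and 4.01-fold for the cell cycle regulator RGCC. SPINK4, a protease inhibitor, rose 3.29-fold, CLIC3, a chloride channel family member, 3.22-fold, and the hair keratin-associated gene KRTAP2-4, whose family members are near-identical, 7.95-fold.

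All 3 NF-kB lists fell with siRelA. Of the cytokines and chemokines 15 of 22 fell (18 adjusted over the list alone), with a median of -2.53 (camera adjusted p = 1.42e-28, and 0.00475 with an estimated correlation). CXCL10 was at least 9.04-fold lower, CSF2 10.2-fold, the chemokine CCL20 9.25-fold, IL6 6.65-fold (adjusted p = 0.0162), CXCL1 5.98-fold and TNF at least 2.71-fold lower. Of the feedback genes 7 of 21 fell (14 adjusted over the list alone), with a median of -0.91 (camera adjusted p = 6.39e-16, and 0.0121 with an estimated correlation). BIRC3 fell 6.51-fold, TNFAIP3 4.92-fold, NFKBIA 4.85-fold, the signalling kinase gene IRAK2 4.39-fold and TNIP1 2.73-fold. Of the adhesion, survival and tissue genes 7 of 22 fell (14 adjusted over the list alone), with a median of -1.14 (camera adjusted p = 2.49e-13, and 0.00475 with an estimated correlation). ICAM1 was at least 6.90-fold lower, TNFAIP2 fell 2.95-fold and the transcription factor IRF1 2.83-fold.

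Other lists also moved with siRelA. Interferon-stimulated genes had a median of -0.30 (camera adjusted p = 2.24e-07, and 0.00475 with an estimated correlation), and 6 of 31 fell (8 adjusted over the list alone), among them the RNA sensor IFIH1 (2.68-fold), the antigen transporter TAP1 (2.33-fold) and PSMB9 (at least 2.20-fold). Hypoxia genes had a median of -0.38 (camera adjusted p = 5.32e-06, and 0.00475 with an estimated correlation), with 1 of 21 down (5 adjusted over the list alone), the glycolysis regulator PFKFB4 (1.62-fold). In the authors' processed values the hypoxia list did not pass (-0.21, adjusted p = 0.0609). Of 8 blood cell markers, 1 fell in either adjustment, adjusted over the list alone included, LCP1 (3.63-fold), and the list's median was -0.20 (camera adjusted p = 0.00438, and 0.0396 with an estimated correlation), against -0.01 without a detection filter (adjusted p = 0.361). The stress response list had a median of -0.33 (camera adjusted p = 0.0018, and adjusted p = 0.478 with an estimated correlation), and DDIT4, an mTORC1 inhibitor, fell 1.84-fold. That list's call was lost without siNC replicate 2 (median -0.15, adjusted p = 0.169), without both replicate 2 arrays (0.105), in the second processing set (0.0639) and in the authors' values without or with a set term (0.128 and 0.162). Immediate early genes had a median of 0.37 (camera adjusted p = 0.00781, and adjusted p = 0.211 with an estimated correlation), with DUSP1, a MAP kinase phosphatase gene, up 2.88-fold, and the replicate block gave an adjusted p of 0.0602. The 8 other lists did not pass (camera adjusted p from 0.252 to 0.983). The cholesterol list (median 0.12) passed as higher without siNC replicate 2 (0.31, adjusted p = 0.00056), without both replicate 2 arrays (0.32, 7.52e-05), in the second processing set (0.32, 0.000141) and in the authors' values with a set term (0.19, 0.0118). Among their members, FBXO32, a ubiquitin ligase gene, was 3.71-fold lower, with another, dim probe at 0.08, and ERBB3, a receptor kinase gene, 1.75-fold higher, with other probes at 0.33 and -0.16.

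With the replicate block and an estimated correlation, the siRelA cytokine and hypoxia lists passed (adjusted p = 0.0303 each), and the feedback (0.0879), adhesion (0.0811), interferon (0.0811) and blood cell (0.0853) lists did not. With siRelA 77 genes were higher and 168 lower, 245 together. The replicate block gave 1811 genes (876 higher and 935 lower, all 245 included), the second processing set alone gave 2143, and the first set holds no siRelA array. Leaving out siNC replicate 2 gave 462 genes, the siNC TNF array 102, the siRelA array without TNF 42 and the siRelA TNF array 40, and of 41 named genes past the threshold 7 passed whichever array was left out.

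The siRelB comparison addressed the same question for RELB. CEMIP was 18.1-fold lower with siRelB (log2 change -4.18 ± 0.39, 2 arrays against 4, adjusted p = 0.000597), CXCL10 7.99-fold, SCG5 7.28-fold and IL6 7.10-fold (adjusted p = 0.0207). CXCL11 was at least 5.79-fold lower, MAL2, a transport membrane protein gene, at least 5.74-fold, ALOX5AP, which acts in leukotriene synthesis, 6.07-fold and LCN2 6.01-fold. Rises were led by PLCXD1, a phospholipase-like gene not detected with siNC (at least 2.996-fold), SNCAIP, a synuclein-interacting protein gene (3.07-fold), LOC388610 (2.93-fold), SERINC2 (2.89-fold), the glutathione transferase GSTP1 (2.82-fold), IGFBP3 (2.79-fold), the ubiquitin ligase MARCHF4 (2.75-fold) and RGCC (2.66-fold).

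Of the NF-kB cytokines and chemokines 6 of 22 fell with siRelB (13 adjusted over the list alone), with a median of -1.39 (camera adjusted p = 2.72e-18, and 0.00796 with an estimated correlation). Besides CXCL10, CXCL11 and IL6 these were CSF3 (4.24-fold), the lymphotoxin LTB (3.14-fold) and the chemokine CX3CL1 (at least 2.38-fold). CXCL8 changed by -1.08 ± 0.44 (adjusted p = 0.41) and CXCL1 by -0.93 ± 0.47 (adjusted p = 0.555), so neither passed. RELB itself was the 1 feedback gene of 21 that fell, in either adjustment, adjusted over the list alone included (median -0.42, camera adjusted p = 1.95e-05, and adjusted p = 0.149 with an estimated correlation). BIRC3 changed by -0.96 ± 0.29 (adjusted p = 0.211), NFKBIA by -0.72 ± 0.36 (adjusted p = 0.548) and TNFAIP3 by -0.20 ± 0.33 (adjusted p = 0.919). None of the 22 adhesion, survival and tissue genes passed over all genes and 9 fell adjusted over the list alone, while the list was lower (median -0.34, camera adjusted p = 2.02e-07, and 0.0182 with an estimated correlation). ICAM1 changed by -1.49 ± 0.40 (adjusted p = 0.146).

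Interferon-stimulated genes were lower with siRelB (median -0.21, camera adjusted p = 5.97e-07, and 0.00796 with an estimated correlation), and 3 of 31 fell (7 adjusted over the list alone), namely PSMB9 (2.01-fold), the antiviral tether BST2 (at least 1.35-fold) and IFIT2 (1.72-fold). Hypoxia genes had a median of -0.40 (camera adjusted p = 3.9e-08, and 0.00623 with an estimated correlation), with 1 of 21 down (3 adjusted over the list alone), the glucose transporter SLC2A1 (1.77-fold). The stress response list had a median of -0.61 (camera adjusted p = 7.14e-10, and adjusted p = 0.159 with an estimated correlation), with DDIT4 down 2.83-fold and 4 of 21 down adjusted over the list alone. The 10 other lists did not pass (camera adjusted p from 0.0597 to 0.915). The blood cell list (median -0.25) passed as lower under median scaling (adjusted p = 0.0383), in the authors' values (0.044), in these with a set term (0.0062) and without siEZH2 replicate 1 (0.0454). The cholesterol list passed as higher in the second processing set (median 0.17, adjusted p = 0.0473). In another of them FBXO32 fell 2.09-fold, with another, dim probe at 0.40.

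With the replicate block and an estimated correlation, the siRelB hypoxia list passed (adjusted p = 0.023), and the cytokine (0.0712), adhesion (0.158) and interferon (0.158) lists did not. With siRelB 46 genes were higher and 96 lower, 142 together, and in the authors' processed values 22 were higher and 26 lower, 48 together. The replicate block gave 1569 genes (727 higher and 842 lower, all 142 included), the second processing set alone gave 1927, and the first set holds no siRelB array. Leaving out siNC replicates 1, 2 or 3 gave 88, 333 and 72 genes, siEZH2 replicate 2 218, the siNC TNF array 30, the siEZH2 TNF array or either siRelA array 85, the siRelB array without TNF 15 and the siRelB TNF array 20, and of 26 named genes past the threshold 8 passed whichever array was left out.

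The TNF comparison asked which genes respond to TNF on average over the 4 siRNAs. As lists, cytokines and chemokines were higher with TNF (median 0.66, camera adjusted p = 1.66e-22, and 0.0112 with an estimated correlation), as were feedback genes (median 0.50, camera adjusted p = 1.66e-22, and 0.0112 with an estimated correlation) and adhesion, survival and tissue genes (median 0.31, camera adjusted p = 1.96e-08, and 0.016 with an estimated correlation). No single gene passed over all genes, whereas 13 of 22 cytokines, 9 of 21 feedback genes and 2 of 22 adhesion genes rose adjusted over the list alone. TNFAIP3 averaged a change of 1.48 ± 0.24 (adjusted p = 0.384), BIRC3 of 1.36 ± 0.21 (adjusted p = 0.384), CXCL8 of 1.48 ± 0.32, IL6 of 1.10 ± 0.34, NFKBIA of 0.81 ± 0.26 and ICAM1 of 0.56 ± 0.29, with 4 of 4 siRNAs higher for each of these genes. The 13 other lists did not pass (camera adjusted p from 0.102 to 0.786). In the authors' processed values the replication list (median -0.14, adjusted p = 7.16e-10) and the mitosis list (-0.23, adjusted p = 1.88e-10) passed as lower and the hypoxia list as higher (0.18, adjusted p = 0.0137). With a set term these values gave smaller medians, -0.03 for replication (adjusted p = 0.00116) and -0.06 for mitosis (0.0114), and the hypoxia list did not pass. The authors' values are centred per processing set, and every TNF array is in the second set. Arrays with siEZH2, where both cell cycle lists are lower, are a larger share of the first set. Calls without a set term therefore cannot be separated from that centring. The mitosis list also passed as lower in the second processing set (-0.06, adjusted p = 0.0309), and the cholesterol list under median scaling (-0.13, 0.0422). Between the siNC arrays alone (1 against 3) the stress response list had a median of -0.20 and the cholesterol list one of -0.36. On siNC replicate 2, a control in that comparison, these lists lay above the other siNC controls by medians of 0.723 and 0.985. Their lower values with TNF therefore cannot be told apart from a deviation of that control array. limma called 0 genes, with 219 at an unadjusted p under 0.05 where 614 are expected from unchanged genes, and with the replicate block 0 genes, with 520 at an unadjusted p under 0.05. Without siEZH2 replicate 2 CSF2 passed (log2 change 1.44 ± 0.12, adjusted p = 0.00909). Without siNC replicate 1, siNC replicate 3 or the siEZH2 TNF array the cholesterol list passed as lower (adjusted p = 0.0311, 0.026 and 0.0272) as did the stress response list (0.0111, 0.026 and 0.0272). Each of these fits keeps siNC replicate 2, so the same limit holds. The second processing set alone gave 0 genes with 881 at an unadjusted p under 0.05.

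Within each siRNA the response was read from 1 TNF array and has no replicate check. The median change of the cytokine list was 0.63 with siNC, 0.69 with siEZH2 and 0.68 with siRelB, each at percentile 100 of matched random lists, and 0.17 with siRelA (percentile 99.95). The order of siNC, siEZH2 and siRelB was not stable, with 0.532, 0.446 and 0.329 without background correction. Its difference from siNC was -0.32 with siRelA (percentile 0), 0.15 with siEZH2 (percentile 98.8) and 0.04 with siRelB (percentile 76.9), the last being -0.05 without background correction. These percentiles compare genes and not arrays. Among control arrays alone, a similar difference between siEZH2 and siNC reached 0.635 for the cytokine list and 0.547 for the adhesion list in absolute size. For cytokines 13 of 18 control values were as large as the observed siEZH2 difference. The control values set single arrays against each other, whereas the observed difference used the mean of 3 controls per siRNA. Control values would thus vary more, and that count is no measure of chance. Feedback genes changed by a median of 0.37 with siNC, 0.74 with siEZH2, 0.21 with siRelA and 0.55 with siRelB, and adhesion, survival and tissue genes by 0.42, 0.48, 0.09 and 0.46. The differences from siNC of the feedback list were 0.32 with siEZH2 (percentile 100), -0.17 with siRelA (percentile 1.85) and 0.35 with siRelB (percentile 100), or 0.26, -0.38 and 0.12 with replicate 3 alone as control, and those of the adhesion list 0.01, -0.43 and 0.13 (percentiles 67.1, 0 and 98.4), the last being -0.14 in the authors' processed values.

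The 5 largest rises with TNF were NF-kB targets with siNC, siEZH2 and siRelB, and included other genes with siRelA. With siNC these were TNF (1.41), LTB (1.35), CX3CL1 (1.35), CCL20 (1.33) and TNFAIP2 (1.26). With siEZH2 they were CCL20 (3.43), the chemokine CXCL2 (2.76), CXCL8 (2.38), CSF2 (2.33) and TNFAIP3 (2.24). With siRelA CXCL8 (1.53) and CSF2 (1.35) led, followed by JOSD2, AKAP1 and NECAB3 (0.92, 0.88 and 0.86), and with siRelB BIRC3 (1.71), CXCL2 (1.66), the adaptor TRAF1 (1.65), CSF2 (1.64) and CCL20 (1.62). CLEC2D, a lectin-like receptor gene, had the lowest value with siNC (-1.84, a larger change than any rise) and with siEZH2 (-1.77), followed with siNC by NCMAP (-1.73), MAPK14 (-1.12), SPTBN1 (-1.09) and TRPV4 (-1.07) and with siEZH2 by SPTBN1 (-1.17), KCNV2 (-1.05), ZNF114 (-1.02) and ECD (-0.95). The lowest values were -1.02 with siRelA (IRF1) and -0.93 with siRelB (CSMD1). CLEC2D and SPTBN1 were not among the 5 largest falls with siRelA or siRelB. Controls with siNC and siEZH2 average 3 arrays over both processing sets, whereas siRelA and siRelB have 1 control array each. Falls of these 2 genes therefore cannot be told apart from differences between control arrays.

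**Figure D2:**
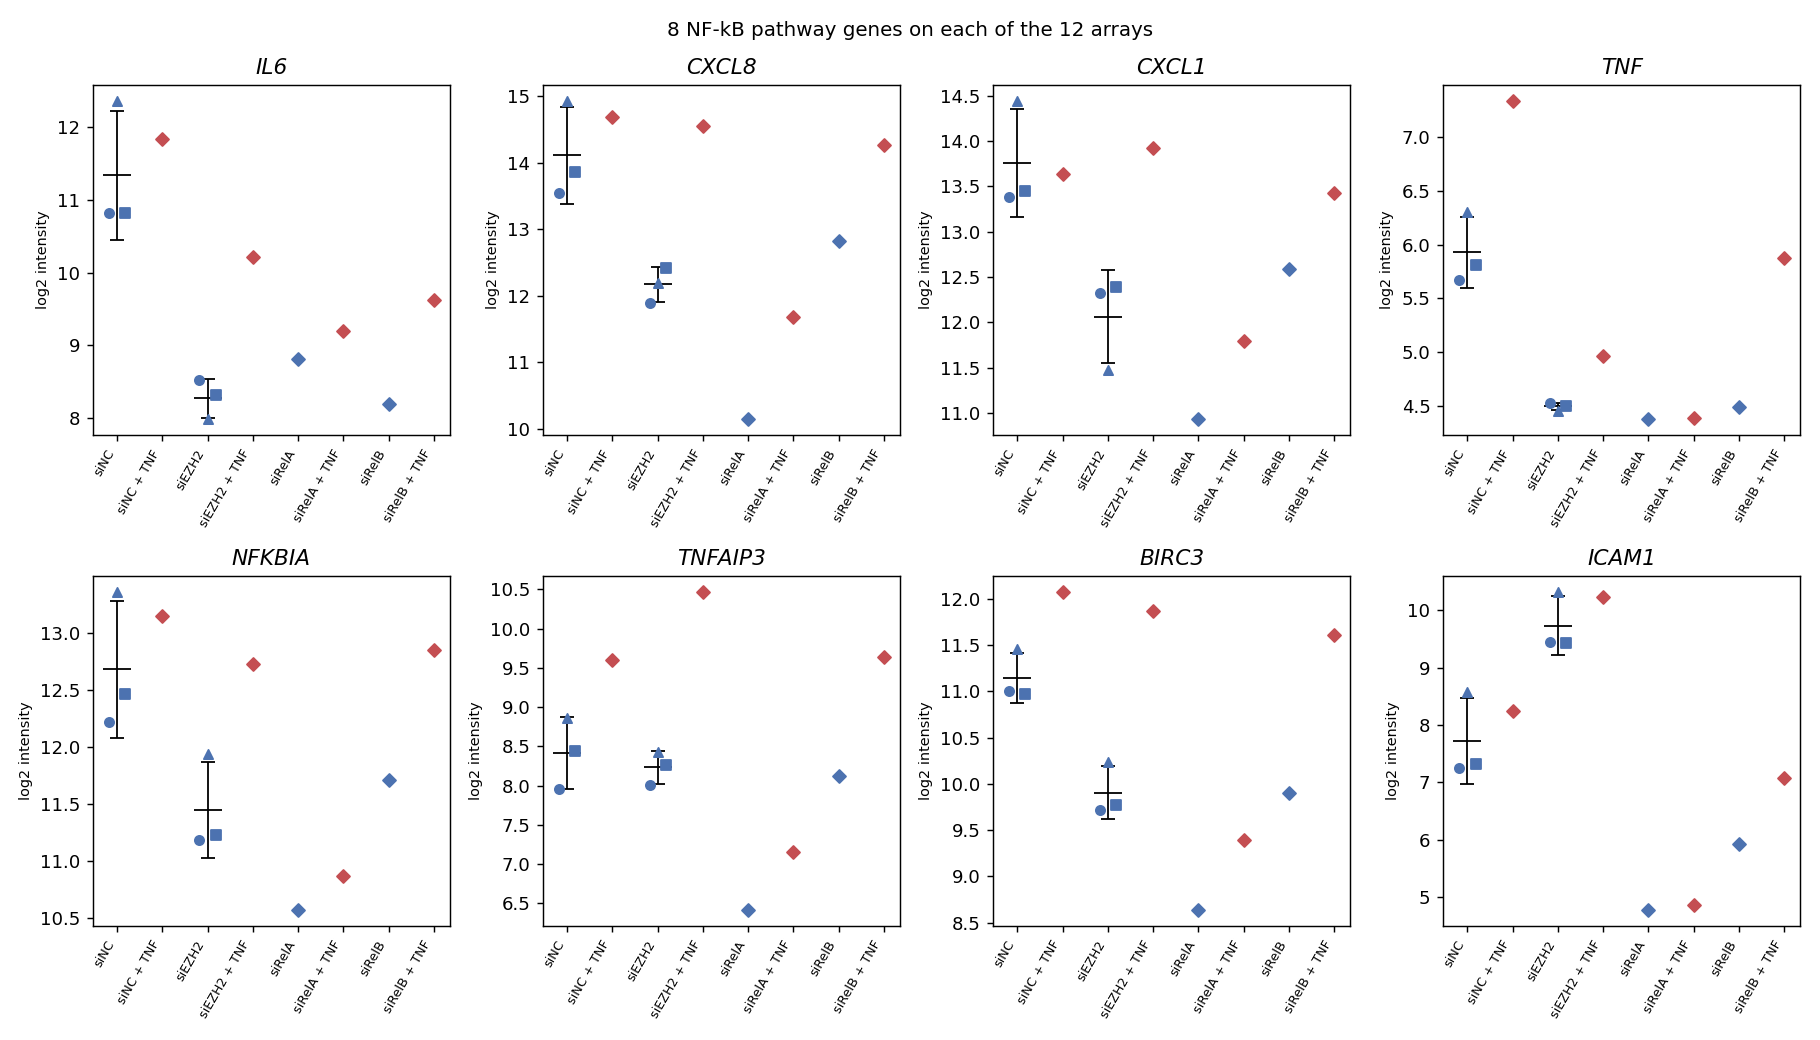
Normalized log2 intensity of NF-kB genes on each array, by siRNA, with arrays without TNF in blue and with TNF in red. Circles, triangles and squares are replicates 1, 2 and 3, diamonds are groups of 1 array, and black bars give the mean ± SD of 3 arrays. IL6 without TNF averages 11.34 with siNC and 8.27 with siEZH2, and reads 8.81 with siRelA and 8.19 with siRelB.

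The interaction asked whether the TNF change differed between siEZH2 and siNC. CXCL1 changed by 1.86 with siEZH2 and by -0.12 with siNC, a difference of 1.98 ± 0.74, CXCL8 differed by 1.80 ± 0.73, IL6 by 1.44 ± 0.86, TNFAIP3 by 1.06 ± 0.53, BIRC3 by 1.03 ± 0.46 and TNF by -0.94 ± 0.42, and the limma adjusted p was 1 for each. Feedback genes as a list had a larger TNF change with siEZH2 (median difference 0.32, camera adjusted p = 3.53e-07, and adjusted p = 0.396 with an estimated correlation). The mitosis list (median 0.32, camera adjusted p = 3.58e-05, and adjusted p = 0.638 with an estimated correlation) and the cholesterol list (median 0.32, camera adjusted p = 0.0167, and adjusted p = 0.638 with an estimated correlation) passed too. Cytokines did not pass (median 0.15, camera adjusted p = 0.238), but passed with genes detected at p under 0.01 on all arrays (median 1.31, adjusted p = 3.62e-12) and in the authors' processed values (median 0.12, adjusted p = 0.00562). The 12 remaining lists did not pass. Under median scaling the PRC2 list did (0.15, adjusted p = 0.0499). No member of any list passed adjusted over the list alone. limma called 0 genes with 23 at an unadjusted p under 0.05, and with the replicate block 0 genes with 424 at an unadjusted p under 0.05. The mitosis call was lost without siEZH2 replicate 2 (median 0.05, adjusted p = 0.586), the cholesterol call without siEZH2 replicate 1 (adjusted p = 0.139), siNC replicate 2 (median -0.07, adjusted p = 0.496) or siEZH2 replicate 3 (adjusted p = 0.105) and without a detection filter (0.0519). The stress response list had a median of 0.379 without siNC replicate 1 and of 0.334 without siNC replicate 3. Without both replicate 2 arrays its median was -0.0923.

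The last comparison asked how far the siEZH2 changes overlap those of siRelA and siRelB. With siEZH2 and siRelA, 63 genes were lower in both and 42 higher in both, where independent lists would share 11.6 and 6.07, and 16 and 4 genes went in opposite directions (13.2 and 5.33 for independent lists). With siEZH2 and siRelB 42 genes were lower in both and 27 higher in both (6.64 and 3.63 for independent lists), and 8 and 4 went in opposite directions. The covariance of log2 changes over genes was 0.0517 for siEZH2 with siRelA and 0.0507 with siRelB, against simulated values of 0.0233 and 0.0232, and the correlations were 0.207 and 0.228 against 0.350 and 0.348. The simulated groups were unchanged, whereas each siRNA here also changed genes of its own. The simulated correlations are therefore no measure of chance for the observed ones. With separate siNC arrays (replicates 1 and 2 for siEZH2, replicate 3 and TNF for siRelA and siRelB) the covariances were 0.0483 and 0.0477, the correlations 0.189 and 0.205. In these fits 525 and 497 genes at an unadjusted p under 0.05 in both went in the same direction (296 and 285 for independent lists), against 259 and 219 in opposite directions (294 and 283 for independent lists). The shared totals of 105 and 69 genes became 732 and 640 with the replicate block, where independent lists would share 394.2 and 341.2 and 316 and 238 genes went in opposite directions. With arrays left out they became 59 and 35 without siNC replicate 1, 195 and 146 without siNC replicate 2, 48 and 30 without siNC replicate 3, 51 and 17 without the siNC TNF array, 55 and 41 without siEZH2 replicate 1, 54 and 41 without siEZH2 replicate 3, 22 without the siRelA array without TNF and 23 without the siRelA TNF array, and 7 without the siRelB array without TNF and 10 without the siRelB TNF array.

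Among the 30 genes lower with all 3 siRNAs, 6 belonged to the NF-kB lists, namely CSF3, CX3CL1, CXCL10, CXCL11, IL6 and LTB, and 16 genes were higher with all 3. IL6 changed by -3.07 with siEZH2, -2.73 with siRelA and -2.83 with siRelB. In contrast ICAM1 and MMP1 were among 20 genes called in opposite directions with siEZH2 and siRelA. ICAM1 changed by 2.02 ± 0.42 with siEZH2 and by -3.17 ± 0.40 with siRelA, and MMP1 by 1.73 ± 0.43 and -3.68 ± 0.39. SCG5 rose by 3.72 with siEZH2 and changed by -2.86 with siRelB.

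**Figure D3:**
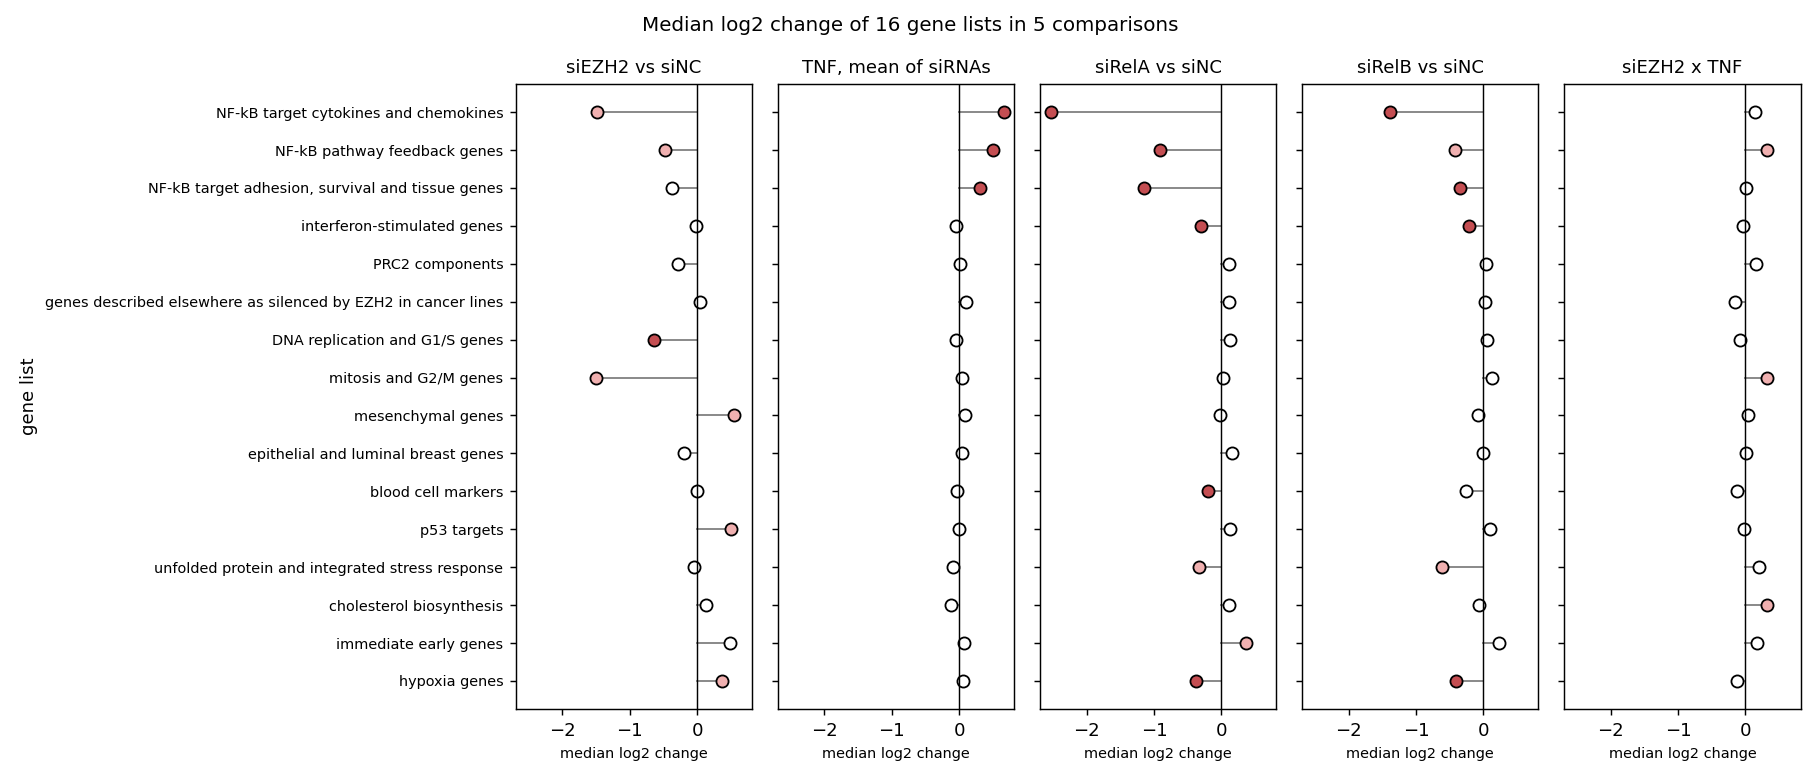
Median log2 change of each of the 16 gene lists in the 5 tested comparisons. Dark red marks lists that pass with both the preset and the estimated correlation, pink those that pass with the preset correlation only, and white those that do not pass. The cytokine list has medians of -1.49 with siEZH2, -2.53 with siRelA, -1.39 with siRelB and 0.66 with TNF.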

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

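Of the tests in this part, the one without both replicate 2 arrays was chosen only after the result was seen. The list tests of the siEZH2 by TNF interaction singled out 3 lists at the preset correlation for a difference in TNF change between siEZH2 and siNC, each resting on 1 TNF array per siRNA. None of the 3 passed with an estimated correlation (adjusted p = 0.396 for feedback genes, and 0.638 for mitosis and for cholesterol genes). NF-kB feedback genes had a median difference of 0.318, as the TNF change was 0.744 with siEZH2 and 0.373 with siNC. TNFAIP3, which encodes A20, changed by 2.24 and 1.18, and BIRC3, an inhibitor of apoptosis, by 1.96 and 0.93. The feedback list also changed more with siRelB than with siNC (0.348), so the difference was not particular to siEZH2. With replicate 3 alone as control the differences were 0.262 with siEZH2 and 0.117 with siRelB. Both rest on the same siNC TNF array, read from a mean of 23.6 beads per probe, whose part was not tested.

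For the feedback list, 3 technical explanations were weighed. The replicate 2 control arrays are argued against as the whole cause, since the median difference was 0.3373 without them. Variation between arrays of a group is not decided. Among control arrays alone, a similar difference of differences reached 0.6158 in absolute size, and 10 of 18 such values were as large as the one observed. These values set single arrays against each other, whereas the observed one used the mean of 3 controls per siRNA. Some also crossed replicate numbers, although same-numbered arrays deviated together. Control values would thus vary more than the observed kind, and their count cannot decide. Compression of bright signals in siNC stays open, because the 10 dimmer members had a median difference of 0.2468. Its approximate standard error over members, not over arrays, was 0.26. The 11 brighter members had a larger one of 0.614, the direction that compression would give. The limit on that standard error, which leaves compression open, was added after the first value was seen. A biological difference between siEZH2 and siNC stays open as well.

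Mitosis genes had a median difference of 0.324 in the same test, and 0.0376 without both replicate 2 arrays. Cholesterol biosynthesis genes had a median difference of 0.32, and 0.0137 without both replicate 2 arrays.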

How the results depend on the processing

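The processing sets, the removal of both replicate 2 arrays, the replicate block outside the siEZH2 comparison, separate siNC arrays and replicate 3 alone as control are tests chosen after the data were seen. For each value below the cause was not tested, beyond the fewer arrays that some alternatives use. With siEZH2 (1817 genes) limma called 950 genes in the authors' processed values, 5348 with the replicate block, 3986 in an additive fit of 4 arrays against 4, 0 in the first processing set (1720 at an unadjusted p under 0.05), 6272 in the second set, 3802 without both replicate 2 arrays, and 611 to 2168 with 1 array left out. With siRelA (245) the counts were 101 in the authors' values, 1811 with the block, 1 without TNF (1 array against 3, VNN1, chosen after its value was seen), 2143 in the second set, 1519 without both replicate 2 arrays and 40 to 462 with 1 array left out. With siRelB (142) they were 48 in the authors' values, 248 in these with a set term, 1569 with the block, 0 without TNF (limma, 327 at an unadjusted p under 0.05), 1927 in the second set, 1347 without both replicate 2 arrays and 15 to 333 with 1 array left out. The share of siRelB calls that were higher was 32.4%, against 45.8% in the authors' values, 46.3% with the block and 43.2% under the strict detection filter, and that of siRelA 31.4%, against 48.4% with the block. Without 1 of its own arrays (CTRL or TNF) it was 7.14% or 12.5% for siRelA and 13.3% or 10% for siRelB. For TNF, limma called 0 genes (219 at an unadjusted p under 0.05), 2 without both replicate 2 arrays (CSF2 and IL1A, chosen after their values were seen, at 1.42 and 1.2) and 0 to 1 with 1 array left out. For the interaction it called 0 genes (23 at an unadjusted p under 0.05), and 0 to 0 with 1 of the 6 replicated arrays left out. Genes shared in direction by siEZH2 and siRelA (105) numbered 228 at an unadjusted p under 0.01, 732 with the block, 620 without both replicate 2 arrays, 525 with separate siNC arrays at an unadjusted p under 0.05 and 22 to 195 with 1 array left out, and for siRelB (69) 188, 640, 565, 497 and 7 to 146. As calls grow, so do the numbers for independent lists, to 394.2 and 341.2 with the block. Of 80 list tests 27 passed, 14 with an estimated correlation, and 26 to 29 with 1 array left out. The replicate block at the preset correlation changed the calls of the immediate early list only, gained with siEZH2 (0.0358, but 0.69 with an estimated correlation as well) and lost with siRelA (0.0602). With the block and an estimated correlation together, 8 of those 14 calls were lost, among them siEZH2 replication (0.436) and siRelB cytokines (0.0712). The block leaves fewer degrees of freedom, so these losses need not come from correlation between genes. The mitosis list under TNF (0.0399) went to -0.231 in the authors' values, -0.0592 in the second set and -0.0607 in the authors' values with a set term. Without that term the value cannot be separated from the centring per set, as every TNF array is in the second set. The cholesterol list with siRelB (-0.0636) went to 0.173 in the second set, and in the interaction (0.32) to -0.0666 without siNC replicate 2, with a range of -0.0666 to 0.465 when 1 array was left out. TNF changes of the cytokine list without background correction were 0.532 with siNC, 0.446 with siEZH2 and 0.329 with siRelB, of the feedback list 0.578 with siEZH2, 0.144 with siRelA and 0.435 with siRelB, and of the adhesion list 0.345 with siNC, 0.412 with siEZH2 and 0.378 with siRelB. In the authors' values they were 0.88 with siNC and 0.463 with siRelB for cytokines, 0.294, 0.607 and 0.468 with siNC, siEZH2 and siRelB for feedback genes, and 0.508, 0.676 and 0.399 for adhesion genes. With replicate 3 alone as control they were 0.813 and 0.571 with siNC and siEZH2 for cytokines, 0.549 and 0.811 for feedback genes, and 0.328 with siNC for adhesion genes. The siRelB difference from siNC went to -0.0463 for cytokines without background correction and to -0.144 for adhesion genes in the authors' values. Over the named genes and these alternatives, calls were lost 241 times with siEZH2, 172 with siRelA and 129 with siRelB, gained 11, 0 and 7 times, and reversed 0 times. A slide block was not run, as the files name no slides. Signal over background limits dim genes, with 55.6% to 58.2% of probes detected per array.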

Other observations

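The tests chosen only after the result was seen in this part are the splits for siEZH2, the swap of the replicate 2 arrays, and those of other siRNAs and of off-target effects for mitosis genes. The genes named in this part outside the naming rule were chosen after their values were seen. Single genes of the stress response list, which did not shift as a whole, went in opposite directions with siEZH2 (3 arrays against 3, limma). ASNS, asparagine synthetase, changed by -2.08, and the serine synthesis genes PHGDH and PSAT1 by -1.89 and -1.63 (adjusted p = 0.00374 for PSAT1). HSPA5, the main chaperone of the endoplasmic reticulum, rose by 2.40, and CHAC1, which degrades glutathione, by 1.13 (adjusted p = 0.00777).

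Several genes outside the fixed lists changed in the same direction with all 3 siRNAs. ALOX5AP, which acts in leukotriene synthesis, changed by -2.76 with siEZH2, -2.64 with siRelA and -2.60 with siRelB, PTGES, a prostaglandin E synthase, by -2.43, -1.90 and -1.74, and the cytokine subunit IL23A by -2.27, -1.91 and -1.64. The immunoproteasome subunit PSMB10 changed by -1.46, -0.78 and -0.70. Higher with all 3 were the chemokine receptor CXCR4 (1.88, 1.43 and 1.34) and the matrix gene ECM1 (1.71, 1.43 and 1.34). VNN1, a pantetheinase, rose with siEZH2 (1.53) and fell with siRelA (-4.61).

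With siEZH2, 56 genes went from undetected on the 3 siNC arrays to detected on the 3 siEZH2 arrays, and 33 went the other way, a ratio of 1.697. The other 9 splits of these arrays gave at most 15 genes in either direction, but each mixes siNC and siEZH2 arrays, so they do not bear on the ratio. Those turned on included MUC1, a membrane mucin, the intermediate filament gene NES, GPNMB, a membrane glycoprotein gene, and the growth factor BMP2. The ratio goes with loss of silencing as a hypothesis but cannot decide it, because detection also differed between arrays. The fewest probes were detected on siNC replicate 3 (12337) and the most on siEZH2 replicate 3 (12908). Among the genes turned on were 0 members of the list of genes described elsewhere as silenced by EZH2.

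Of the 10 splits of the 6 arrays into 3 against 3, 1 gave as many genes as siEZH2 against siNC, the real one with 1817, and the highest other count was 0 by limma. The splits are too few for a share under 0.05. The other 3 splits that part all 3 pairs also gave 0, and each of them mixes siNC and siEZH2 arrays. For TNF, 12 of 64 splits within siRNAs, the real one included, gave as many genes at an unadjusted p under 0.05 as the real 219. Each of the others marked siNC replicate 2 or both replicate 1 arrays, and same-numbered arrays deviated together. The median of the splits other than the real one was 126. Chance is therefore not excluded for the count of 219, but the 12 splits do not measure it. The highest other count was 5147, from a split marking both replicate 2 arrays, with 2208 genes at an adjusted p under 0.05, which points to a structure of the samples.

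The replicate 2 arrays of siNC and siEZH2 stood apart, at 66.2 and 38.0 on a component with 28.0% of the variance where no other array exceeded 0. In both, CDC14B, a phosphatase gene, and INSIG1, a sterol sensor, were higher than in the other replicates (mean deviations 3.22 and 2.54), and KISS1 and the early growth response gene EGR1 lower (-2.56 and -2.12). Higher background is argued against, as the deviations of the pair correlated at 0.8275 over the brightest genes. A swap of the pair is argued against by EZH2, which was -2.83 on the siEZH2 array relative to siNC. Cells of a luminal line are argued against by the epithelial and luminal list, whose median deviation was -0.2311. Its approximate standard error over genes, not over arrays, was 0.2. Of the 16 lists, cholesterol genes deviated most in siNC (median 0.985, and 0.444 in siEZH2), followed by the stress response list (0.723, and 0.0837 in siEZH2). In siEZH2 the mitosis list deviated most (-0.909, and -0.073 in siNC). No biological explanation was tested, since the labels give none.

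Mitosis genes fell with siEZH2 by a median of -1.5, although the list did not pass camera with an estimated correlation (adjusted p = 0.258). Scaling of the arrays is argued against, as the smaller fall under median scaling and in the authors' values was -1.32, and so is transfection with any siRNA, since the lower of the siRelA and siRelB medians was 0.0324. An off-target effect of the siEZH2 oligonucleotides cannot be told apart from loss of EZH2, because their sequences are not in the labels and the median of -1.5 would be the same under either.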
